A study of Thermus thermophilus HB27 with 6 samples.

How the data were processed

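The series holds 6 RNA-seq libraries of Thermus thermophilus HB27, a thermophilic bacterium with a chromosome and the megaplasmid pTT27. There were 3 libraries of the wild type and 3 of a strain without ago, the gene of its Argonaute protein. The design text describes the 3 libraries per strain as biological replicates. Per the labels' protocols, total RNA was isolated with the mirVana kit from cultures at an OD600 of 0.5, and the temperature is labelled 65 with no unit. Illumina libraries were made from it, and whether they kept the strand is not given in the sources used here.

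Per the file header, the deposited values are the percent of counts mapped on the HB27 genome. Each library summed to 100 percent over 2272 rows, which are 2210 protein-coding genes, 47 transfer RNA genes and 15 predicted RNAs. No ribosomal RNA gene was among the rows. The aligner, the counting program and the genome accession are not given in the sources used here. The authors also deposited a ratio, its log2 value and a p-value per row. Tested on the values, the authors' ratio equals the knockout mean over the wild-type mean, and the deposited p-value equals that of a 2-sided pooled-variance comparison of the 6 percent values, within 5.22e-06. Gene names, products and coordinates are those of the table, and the reference annotation given for another strain of the species matched no locus tag and was not used here. Gene boundaries are translation starts and stops, so lengths are coding lengths. The Argonaute gene is the locus tag TT_P0026, which the table lists as a hypothetical protein. Genes that overlap, lie antisense to each other or have near-identical copies, such as transposases and transfer RNA genes, are uncertain, since the counting rules are not stated.

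Read depth is unknown. All 374 values below 0.001 percent were whole multiples of a step per library, with a tolerance of 0.1 of a step. A step fixed in advance would give 20 percent by chance. Each step was fitted to these same values, so that percentage is not a strict comparison. The steps differed between libraries, from 3.07e-08 to 6.61e-08 percent, too fine for a unit to be a read, and no count was recovered. For this reason no interval or detection limit that needs a read count is given.

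Percent values were multiplied by 10000 to give CPM. Rows with at least 1 CPM in at least 3 libraries were tested, or in as many libraries as the smaller strain had when a library was left out. This kept 2267 rows. Strains were compared with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a trended prior variance, 2-sided, and Benjamini-Hochberg adjustment over all rows. A call is an adjusted p below 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The design fixed before the data were examined named a count-based test, which these values do not allow, so the limma fit that it named for normalized values was used. No scaling beyond the authors' total was applied.

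The method was tested on simulated data with 200 genes changed 1.5-, 2- or 4-fold among the 2267 rows, in 20 draws with variances drawn from the fitted prior of each strain. Without rescaling of the libraries, limma recovered 67.1% of the 1.5-fold, 96.1% of the 2-fold and 99.9% of the 4-fold changes, and 5.63% of calls were false on average. With each simulated library rescaled to 100, as in the deposited values, 9.21% of calls were false on average and 19.3% in the worst draw. Median ratio scaling brought the mean back to 5.56%. An earlier version of the simulation, with 10 draws and the SDs of 3 libraries shuffled over genes as true SDs, gave 36.5% false calls over all draws and 15.4% in the median draw. Its worst draw shifted all genes by 0.25 on the log2 scale. That version was replaced after its result was seen, because shuffled SDs from 3 libraries overstate the spread of true variances. The same shuffling over 20 draws gave 15.3% on average. In the deposited data the median log2 fold change of all rows was 0.02, against a median shift of 0.07 in the rescaled draws. In the same 20 draws, camera called a list of 30 genes raised 1.5-fold in 20 and an untouched list in 0, and the test of placement along the genome passed an unadjusted p of 0.05 in 2 draws of randomly placed changes. Errors were drawn independently for each gene and list members at random. These draws therefore cannot show how often lists or neighbours that vary together are falsely called.

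Before the data were examined, 32 gene lists were fixed as text patterns on names and products. After the corrections given below, 29 had at least 5 tested members. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, 2-sided, adjusted over the 29 lists. Patterns that caught false members or missed the wording of the table were corrected from product names after values had been seen, and the first patterns were kept as an alternative. The first pattern for transfer RNA genes matched 0 genes, so all 47 members of that list were set in this way. The pilus list went from 47 to 23 matched genes, and the citrate cycle list from 21 to 15. Shares of counts were compared by exact 2-sided permutation tests, which cannot go below 0.1 with 3 against 3. Neighbouring calls were counted as adjacent gene pairs called in the same direction, against 100000 random placements of the calls within each replicon.

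Named genes were chosen by a rule fixed before the data were examined. The rule took ago and the 5 genes on each side. It took the 12 largest rises and 12 largest falls among called genes with a mean of at least 10 CPM and no overlap between strains. It also took up to 2 called members per list and direction, or the 2 members of smallest p, as values only, for a list with none. The rule named counts, for which CPM stood in. Runs of adjacent genes, and genes named only as part of them, were chosen after their values were seen.

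Alternatives covered median ratio scaling, no filter, the replicate number as a block, robust estimates, pseudocounts of 0.1 and 10, transfer RNA or megaplasmid genes left out, stricter thresholds and each library left out. Those added after seeing the data were quantile normalization, a minimum of 50 CPM, library weights, predicted RNAs left out, a background per base subtracted, and the gene list patterns as first written. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.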

Results

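Transcript levels were measured in 3 cultures of Thermus thermophilus HB27 and 3 of its ago knockout, each as a percent of the counts mapped on the HB27 genome. Wild-type libraries were more alike than knockout libraries. Across genes, Pearson's r of log2 values was 0.995 to 0.996 within the wild type, 0.979 to 0.981 within the knockout and 0.959 to 0.969 between strains (genes are not independent replicates). The median SD of log2 values was 0.08 in the wild type and 0.18 in the knockout, a ratio of 2.41. Read depth is unknown. Levels below are CPM, given as mean ± SD with n = 3 per strain, and coordinates are those of the authors' HB27 table.

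The transcript of ago (TT_P0026, megaplasmid, 22997 to 25054, minus strand) was nearly absent from the knockout. Argonaute is a nuclease guided by short nucleic acids that acts against invading plasmid DNA in this host. Its level was 174, 160 and 172 CPM in wild-type libraries 1, 2 and 3, and 0.288, 0.103 and 0.00186 CPM in knockout libraries 1, 2 and 3. The log2 fold change was -7.24 (SE 0.15, limma adjusted p = 3.84e-08), a value set in part by the pseudocount. The authors' deposited table gives a ratio of 0.000775 for the knockout over the wild type.

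Genes on the same strand beside ago also fell. The alkaline phosphatase gene TT_P0024 (19903 to 21408) went from 480 ± 86.1 to 154 ± 10.3 CPM, a log2 fold change of -1.62 (SE 0.14, limma adjusted p = 0.000165). The surE gene TT_P0028 (25702 to 26436), annotated as a survival protein, fell by 2.00 on the log2 scale (SE 0.26), and the hypothetical gene TT_P0029 (26446 to 27210) fell by 2.49 (SE 0.37). Of the 10 genes around ago, 3 fell (3 adjusted over the list alone) and 7 did not pass, the 3 being those on the minus strand. Values on the plus strand were 0.02 for TT_P0025, -0.50 for TT_P0027 and 0.06 for TT_P0030. The list was called by camera (adjusted p = 0.021), with an adjusted p of 0.363 with an estimated correlation, and it was not called without knockout library 1 (adjusted p = 0.069) or with library weights (0.0516).

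**Figure D1:**
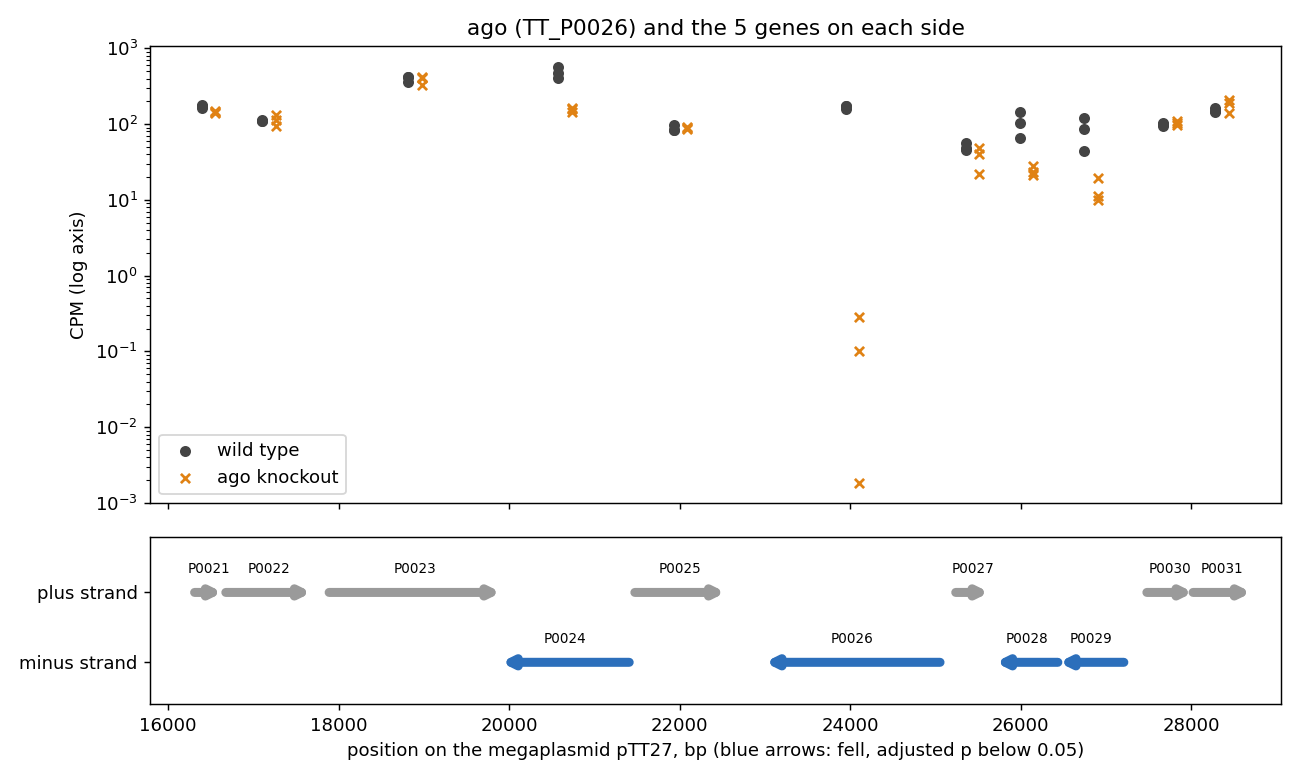
CPM of ago and the 5 genes on each side in each of the 6 libraries (upper panel, log axis), over a map of the genes by position in bp and strand on the megaplasmid (lower panel, blue arrows fell at a limma adjusted p below 0.05). The knockout libraries lie at or below 0.288 CPM at ago, and TT_P0024, TT_P0028 and TT_P0029 are the neighbours that fell.

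The largest single-gene changes included rises of transporter and phenylacetate degradation genes and falls of proline breakdown genes. The largest rise was in livH (TTC0337, chromosome, 321212 to 322069), a permease of branched-chain amino acid transport, from 6.21 ± 0.924 to 31.1 ± 1.48 CPM (log2 fold change 2.16, SE 0.15, limma adjusted p = 9.42e-05). The binding protein gene beside it, TTC0338, rose by 2.10 and the acyl-CoA ligase gene TTC0342 by 1.87. The phenylacetate degradation genes paaZ (TTC0604) and paaD (TTC0605) rose by 1.83 and 1.66, with paaZ going from 660 ± 117 to 2335 ± 175 CPM. Among the largest falls were genes of proline breakdown, 1-pyrroline-5-carboxylate dehydrogenase (TTC1213, -2.13) and proline dehydrogenase (TTC1214, -1.89), with the adjacent gntR regulator gene TTC1215 (-1.80). The acylamino acid-releasing enzyme gene TTC1241 fell from 495 ± 13.9 to 103 ± 12.7 CPM (-2.27).

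Other large rises were in the HAD superfamily hydrolase gene TTC1884 (1.83), the hypothetical genes TTC1472 (1.76), TTC0343 (1.85) and TT_P0045 (1.58), the permease gene TTC0336 (1.82) and livG (TTC0335, 1.75). A leucine transfer RNA gene, TTC3016, rose by 1.72 with a wide spread, 292 ± 226 CPM in the knockout, and its call (adjusted p = 0.0439) was lost when any 1 wild-type library, or knockout library 1 or 3, was left out (adjusted p = 0.052 to 0.126), with megaplasmid genes left out (0.0508) and after quantile normalization (0.0573). Other large falls were in the S-layer protein gene TTC1407, from 3140 ± 260 to 788 ± 72.7 CPM (-1.99), ompH (TTC0475, -1.60) and the multidrug ABC transporter gene TTC0976 (-1.61). The hypothetical gene TTC0442 fell by 1.67. The main S-layer protein gene by level, TTC1532, did not pass (-0.04, SE 0.18).

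In all, 449 of 2267 tested rows were called by limma, 281 higher and 168 lower in the knockout. Of these, 91 had changed at least 2-fold, 57 higher and 34 lower. At an unadjusted p below 0.05 there were 766. The 2 strains did not overlap in 40.0% of rows, against 10% by chance. The authors' deposited table has 658 rows with a p below 0.05, and 428 of the 449 calls are among them. The count of calls was 250, 248 and 237 without wild-type library 1, 2 or 3, and 224 at an adjusted p below 0.01. Tested against a 1.5-fold change, 52 rows were called in place of 91, and falls then outnumbered rises, 30 to 22.

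In the list of branched-chain amino acid and peptide transporters, 19 of 28 tested members rose and 0 fell (20 rose adjusted over the list alone), with a median log2 fold change of 0.65. Those that rose include livM (TTC0081, 1.12), livM (TTC0216, 0.82) and livM (TTC0968, 0.72). Each lies in a run of adjacent genes that rose, TTC0078 to TTC0083, TTC0215 to TTC0220 and TTC0968 to TTC0970. Members of this list are therefore not independent. Dipeptide permease genes did not pass, with 0.25 for dppB (TTC0972) and -0.26 for dppC (TTC0973). The oligopeptide transport genes TTC0098 to TTC0100 (appA, appB and appC) rose by 0.51 to 0.77. The list was called by camera (adjusted p = 5.17e-08), with an adjusted p of 0.363 with an estimated correlation.

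In the fatty acid degradation list 17 of 27 members rose and 0 fell (20 rose adjusted over the list alone), with a median of 0.52. The members that rose include genes of phenylacetate and hydroxyphenylacetate breakdown as well as acyl-CoA metabolism: the phenylacetyl-CoA ligase gene TTC0602 (1.32), the 4-hydroxyphenylacetate monooxygenase gene TTC0594 (0.89), the enoyl-CoA hydratase gene TTC0534 (1.03) and the long-chain fatty acid CoA ligase gene TTC1099 (1.12). Camera gave an adjusted p of 1.79e-07, and 0.363 as the adjusted p with an estimated correlation. Without wild-type library 3, 11 members rose. This list and the transporter list share runs of adjacent genes that rose. The run TTC0333 to TTC0343 holds TTC0342 of this list and TTC0335 and TTC0337 of the other. The run TTC0593 to TTC0608 holds TTC0594, TTC0602 and TTC0604 of this list beside branched-chain amino acid transport genes. In TTC0078 to TTC0083, a long-chain fatty acid CoA ligase gene lies beside TTC0081 of the other list. The lists are therefore not independent of each other, nor are members within a run.

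Of 53 ribosomal protein genes 15 fell and 0 rose (21 fell adjusted over the list alone), 50 had a value below 0, and the median was -0.32. The genes of protein S9 (rpsI, TTC1100) and L1 (rplA, TTC1739) fell by 0.61 and 0.55. Camera gave an adjusted p of 1.12e-09, and an adjusted p of 0.363 with an estimated correlation. The number that fell was 4, 4 and 5 without wild-type library 1, 2 or 3, and 26 without knockout library 2.

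Of 12 cobalamin biosynthesis genes 8 rose and 0 fell, with a median of 0.61, and 8 rose and 1 fell adjusted over the list alone. The methyltransferase genes TT_P0012 and TT_P0013 rose by 0.93 and 0.80. Both lie in a run of 10 adjacent genes that rose, TT_P0010 to TT_P0019, so members of this list are not independent. Camera gave an adjusted p of 0.00125, and an adjusted p of 0.363 with an estimated correlation. In the heat-shock list 5 of 23 members fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.15. The protease genes hslU (TTC0264) and hslV (TTC0265) fell by 1.09 and 0.99, and the chaperonin genes GroES (TTC1713) and GroEL (TTC1714) fell by 0.71 and 0.69, while DnaK (TTC1127) did not pass (-0.26). The rise of clpB (TTC1123, 0.31) was not called after median ratio scaling (adjusted p = 0.0831) or quantile normalization (0.06, adjusted p = 0.602), with library weights (0.0651), nor when any 1 wild-type library (0.140 to 0.205) or knockout library 3 (0.0606) was left out. Camera gave an adjusted p of 0.00531 for the list, and an adjusted p of 0.363 with an estimated correlation.

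Transfer RNA genes had a median of 0.60, and 10 of 47 rose (12 adjusted over the list alone), among them the valine genes TTC3014 (1.55) and TTC3039 (0.70). The call of TTC3039 was lost without wild-type library 1 (limma adjusted p = 0.0644). All members of this list came from a pattern corrected after values had been seen, since the first pattern matched 0 genes. Camera gave an adjusted p of 1.06e-05, and an adjusted p of 0.527 with an estimated correlation. The list was also not called by fry, another test of gene lists (adjusted p = 0.166). The number that rose was 1, 3 and 3 without wild-type library 1, 2 or 3, and 23 without knockout library 3. Their share of counts was 0.785 ± 0.152% in the wild type and 1.20 ± 0.330% in the knockout (n = 3 each, exact permutation p = 0.2). Transposases and integrases had 3 of 17 members that rose (6 adjusted over the list alone), led by TT_P0099 (1.65), with a camera adjusted p of 0.00467 and an adjusted p of 0.418 with an estimated correlation. The list was not called after a background per base was subtracted (adjusted p = 0.0853). The number that rose was 1 when any 1 wild-type library was left out, and 7 without knockout library 2.

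Camera also called the envelope list (3 of 25 fell, adjusted p = 0.021), with TTC1407 and ompH (TTC0475) among those that fell. Its median was -0.05 and its mean -0.21, and 22 members did not pass. The V-type ATP synthase list was called too (1 of 9 fell, median -0.23, camera adjusted p = 0.019). Both had an adjusted p of 0.363 with an estimated correlation, and neither was called without knockout library 1 (adjusted p = 0.127 and 0.0924). Neither was called after quantile normalization (0.0716 and 0.0798), and the V-type list was also not called without wild-type library 1 (adjusted p = 0.0507). Adjusted over the list alone, 3 envelope members and 0 V-type members fell. The V-type member that fell, TTC0911, was not called when any 1 wild-type library (0.0970 to 0.126) or knockout library 1 or 3 (0.0600 and 0.0734) was left out.

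**Figure D2:**
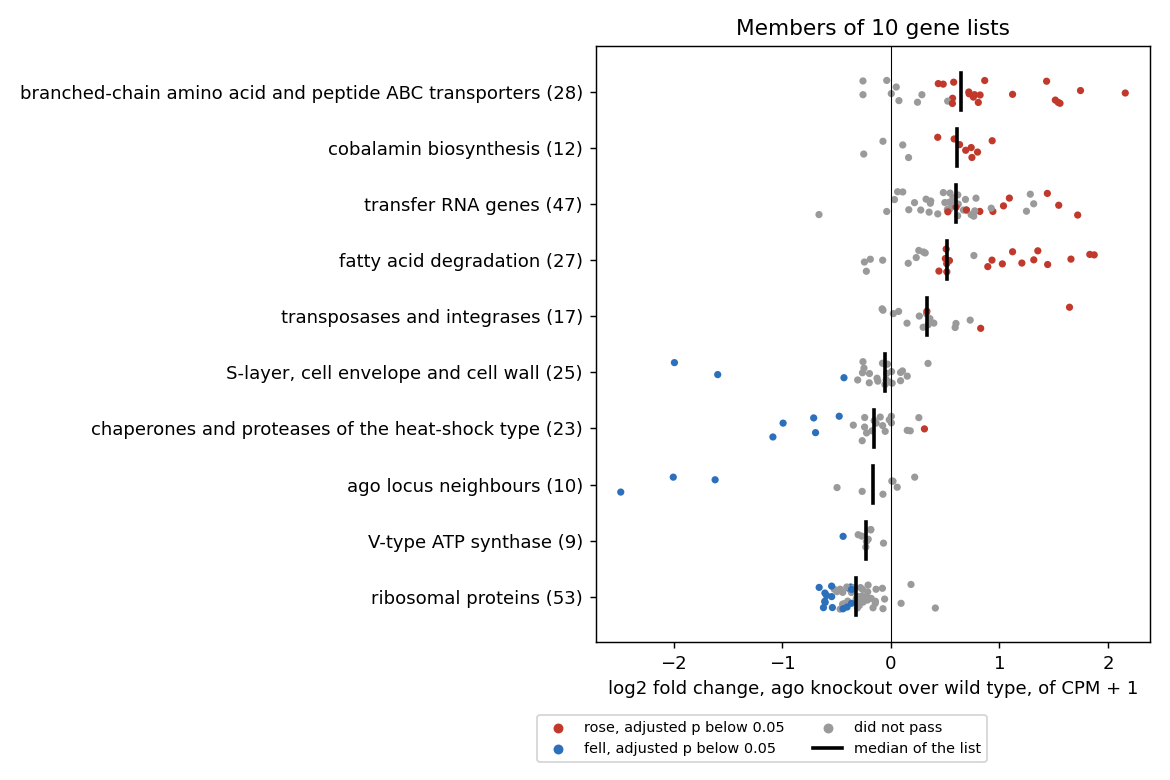
Log2 fold change (knockout over wild type, CPM + 1) of each tested member of 10 gene lists called by camera, with the number of members in brackets. Red points rose and blue points fell at a limma adjusted p below 0.05, grey points did not pass, and black bars are medians, from 0.65 for the branched-chain amino acid and peptide transporters to -0.32 for the ribosomal proteins.

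Of the lists that camera did not call, several held single genes that changed. In the pilus and transformation list 5 of 23 rose (5 adjusted over the list alone), including the prepilin genes TTC0854 (1.01) and TTC0855 (0.86), which were not called after quantile normalization (adjusted p = 0.138 and 0.0546). The number was 3 and 2 without wild-type library 1 or 3, and 8 without knockout library 2. In the carotenoid list 3 of 7 rose (3 rose and 1 fell adjusted over the list alone), with phytoene synthase (TT_P0057) at 1.15 and phytoene dehydrogenase (TT_P0047) at 1.07. Among DNA repair genes, photolyase (TT_P0058), which mends ultraviolet damage, rose by 1.27. Regulators that changed include the response regulator and histidine kinase genes TTC0997 and TTC0998, which fell by 1.16 and 1.01, and the Crp/Fnr family regulator gene TTC1072 (0.66). A sigma-32 factor gene (TTC0468) rose by 0.98. A cytochrome c-552 gene (TTC1058) fell by 1.41, while another gene of that product (TTC0962) rose by 0.77. The maltose transport gene malG (TTC1286) rose by 0.87. In the citrate cycle list 4 of 15 fell (1 rose and 5 fell adjusted over the list alone), among them the succinyl-CoA synthetase gene TTC0169 (-0.47), and the number was 1, 2 and 1 without wild-type library 1, 2 or 3. No member passed among 24 aminoacyl-tRNA synthetases, where the glycyl enzyme gene TTC0175 had -0.29 (adjusted p = 0.0526, and 0.0294 after median ratio scaling). The methionyl enzyme gene TTC0931 had -0.30 (adjusted p = 0.0583, and 0.0351 after median ratio scaling). The same holds for 16 genes of redox defence, 16 of NADH dehydrogenase and 7 of RNA degradation. Alternatives called some of these, among them the ribonuclease gene TTC1171 after median ratio scaling (adjusted p = 0.0424). TTC1822 was called without knockout library 1 (0.0129), and TTC1913 and TTC1919 without knockout library 2 (0.00658 and 0.0107). Of 48 amino acid biosynthesis genes 1 fell (TTC1028, -0.38), a call lost when any 1 wild-type library was left out (0.0545 to 0.112). In other lists, with the number tested, 2 rose and 2 fell of 13 translation factors, 1 and 1 of 12 transcription factors and polymerase subunits, 3 and 6 of 46 regulators, and 3 and 4 of 24 signalling proteins. Of 17 DNA replication genes 0 rose and 1 fell, of 30 repair genes 2 and 1, of 25 cytochrome and electron transfer genes 2 and 2, of 17 glycolysis genes 0 and 2, of 18 sugar transporter genes 3 and 0, and of 22 metal and phosphate uptake genes 2 and 2. Adjusted over the list alone, the numbers that rose and fell were 2 and 3 for translation factors, 1 and 4 for transcription factors and polymerase subunits, 3 and 6 for regulators, and 4 and 4 for signalling proteins. They were 0 and 0 for DNA replication, 1 and 0 for repair, 2 and 1 for cytochromes and electron transfer, 0 and 2 for glycolysis, 3 and 0 for sugar transporters, and 2 and 2 for metal and phosphate uptake. No aminoacyl-tRNA synthetase and no gene of redox defence, NADH dehydrogenase, RNA degradation or amino acid biosynthesis passed in this way. These small counts moved when single libraries were left out. The restriction and toxin list held 1 gene (TTC1296, -0.18), and 0 product names matched the CRISPR-Cas or ribosomal RNA patterns.

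Genes of the megaplasmid were compared because Argonaute acts on plasmid DNA. The megaplasmid took 2.95 ± 0.0383% of counts in the wild type and 3.60 ± 0.105% in the knockout, higher in 3 of 3 knockout libraries than in any wild-type library (exact permutation p = 0.1, the smallest that 3 against 3 can give). Of its 223 tested genes 67 rose and 12 fell (75 and 19 adjusted over the list alone), with a median of 0.20, against 213 and 156 of 2029 on the chromosome, with a median of 0.01. Camera gave an adjusted p of 0.000175, and an adjusted p of 0.363 with an estimated correlation. The number that rose and fell was 64 and 17 after median ratio scaling (median 0.18), 57 and 19 after quantile normalization (median 0.11), 65 and 18 after a background per base was subtracted (median 0.10), and 58 and 4 among genes of at least 50 CPM (median 0.30). Without wild-type library 1, 2 or 3, 48, 39 and 42 genes rose and 5, 6 and 8 fell.

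Changed genes lay next to each other. There were 209 adjacent pairs called in the same direction, against 54.6 under random placement, a ratio of 3.83 (permutation p = 1e-05, the smallest that 100000 placements can give). The calls formed 239 runs, of which 96 held at least 2 genes. The ratio was 5.26, 6.20 and 6.35 without wild-type library 1, 2 or 3, where fewer genes were called. It was 3.32, 3.20 and 3.42 without knockout library 1, 2 or 3, where more genes were called. The longest run was 16 genes from TTC0593 to TTC0608 (chromosome, 575467 to 591485), which hold the homoprotocatechuate and phenylacetate pathways with a branched-chain transporter and rose with a median of 1.34. The second was 11 genes from TTC0333 to TTC0343 (318132 to 327673, median 1.75), and the third 10 genes from TT_P0010 to TT_P0019, which hold precorrin methyltransferase genes (megaplasmid, 7758 to 15942, median 0.72).

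**Figure D3:**
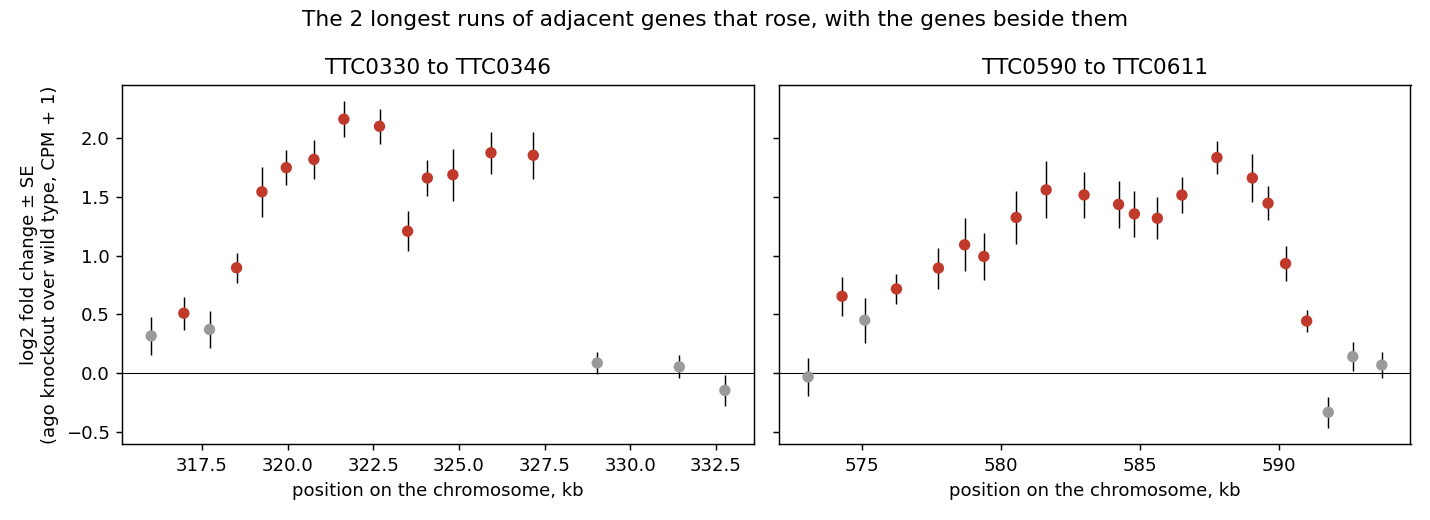
Log2 fold change ± SE (knockout over wild type, CPM + 1) by position on the chromosome in kb, for the runs TTC0333 to TTC0343 and TTC0593 to TTC0608 and the genes beside them. Red points rose at a limma adjusted p below 0.05 and grey points did not pass; the runs have medians of 1.75 and 1.34.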

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

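The fall of ago kept its direction and its call in all 18 alternatives that could be computed, and so did the clustering of calls along the genome in all 8. The differences between strains in the shares of the megaplasmid and of transfer RNA moved by less than the SD pooled over both strains, though some moved by more than the wild-type SD. The count of calls was 224 at an adjusted p below 0.01, and ranged from 237 to 554 when 1 library was left out. It fell when a wild-type library was left out and rose without each knockout library, which are the more variable ones, and the cause was not tested. The count of 2-fold calls was 52 when tested against a 1.5-fold change, with 22 rises and 30 falls in place of 57 and 34. With an estimated correlation 0 gene lists were called in place of 11, and the cause was not tested. Fry called 5 lists that camera did not call, and of the 11 it did not call the transfer RNA list (adjusted p = 0.166). Median ratio scaling gave 487 calls, 429 of them shared with the 449, and quantile normalization, chosen after seeing the data, gave 433 with 389 shared. They put the share of rises at 54.6% and 55.0%, against 62.6%. With the replicate number as a block there were 410 calls, and among the named genes that lost theirs were clpB (TTC1123, adjusted p = 0.161) and the V-type subunit gene TTC0911 (0.0527), while 19 transfer RNA genes rose in place of 10. The deviations of same-numbered libraries correlated at -0.16, 0.27 and -0.13, and not every library correlated best with its own number. Whether numbers pair the samples cannot be told from this, since deviations of 3 libraries from their own mean are tied to each other. Over all pairs of an alternative and a gene named by the rule, 1487 stayed on their side of the threshold, 101 lost a call and 12 gained it. DESeq2, a minimum of 50 counts and RPKM were not run, since no counts or RPKM were used here. Depth is unknown, so what it limits could not be computed.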

Other observations

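Further runs of adjacent genes changed together, and these were chosen after their values were seen. The 7 genes from TT_P0217 to TT_P0223 on the megaplasmid, with beta-galactosidase and alpha-glucosidase genes, rose with a median of 0.64. The genes TTC1049 to TTC1053, with soxB of sulfur oxidation, rose with a median of 0.67 and TTC1284 to TTC1288, with maltose transport genes, with 0.74. The 4 genes from TT_P0049 to TT_P0052, which include a putative ultraviolet damage endonuclease, rose with a median of 0.71. Falling runs, with the median of each run in brackets, included TT_P0177 to TT_P0181 with hemin transport genes (-0.75). They also included TTC0429 to TTC0433, which hold pmbA and tldD (-1.11), and the ribosomal protein genes TTC1310 to TTC1314 (-0.61).

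The tests on scaling, on low levels, on draws of chromosome genes and on the other splits of the libraries for both counts of calls were chosen only after the result was seen. For the 281 genes that rose, a constant background per base in the knockout libraries was set against the loss of ago. The excess was 5.60, 1.71 and 0.692 CPM per kb in knockout libraries 1, 2 and 3, and after its subtraction 95.7% of the rises kept their call. Scaling to 100 percent could also raise genes, and 81.9% kept their call under quantile normalization, the lower of 2 scalings. Neither accounts for most of the rises, while some of those that lost their call may depend on scaling. The strain difference stays open as a hypothesis, as does any difference between cultures that goes with strain.

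For the higher megaplasmid genes, an equal rise of every gene, as more copies of the plasmid might give, was tested by subtracting the median shift of 0.20, after which 62.7% of the rising calls, 42, remained and 25 genes were called lower. A bound on that share, written before the result was seen, was wrong, since 10.5% of chromosome genes also rose with no such shift. In 10000 draws of as many chromosome genes, 12.5% held as many rising calls when matched by level per kb (mean 35.3), and 2.39% when drawn as stretches of 16 adjacent genes (mean 23.4). Low levels, which rose more in the knockout, were tested within 10 classes of level per kb. The difference from the chromosome was then 0.14 (permutation p = 0.0001, the smallest that 10000 can give), 71.3% of the unmatched one. Adjacent genes changed together, and against 10000 draws of stretches of 16 adjacent chromosome genes the p was 0.16. Among the 134 megaplasmid and 1841 chromosome genes of at least 50 CPM, the difference within classes of level was 0.29, with a p of 0.0013 against 10000 such draws. Among these genes a difference from chromosome genes of like level thus remained. However, a gene could pass this filter through its 3 knockout libraries alone. The megaplasmid gene TT_P0058 did so, with 33.2 ± 2.22 CPM in the wild type and 82.5 ± 17.5 in the knockout. The filter may have favoured genes that rose, so the lack of shrinkage does not exclude low level as a cause. Of these megaplasmid genes, 64.9% still lay in the lowest 3 of the 10 classes. Over all genes, where matching shrank the difference and the p against stretches was 0.16, low level also stays open. Along the megaplasmid, 6 of 24 windows of 10 kb had a median below 0. From 170001 to 180000 the median was -0.64, with 7 of 12 genes called lower. An equal rise of every gene, beside further changes of single genes or runs, stays open.

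For the fall of genes beside ago, random placement of large falls was tested. Of 2252 stretches of 5 genes on each side of a gene, 1.73% held as many genes that fell 2-fold, and 9 of these 39 stretches were centred on ago or a gene beside it. A candidate explanation is an effect of the deletion on transcripts of the same strand, which was not tested, since the construct and its marker are not given in the sources used here.

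The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 449 calls and 91 calls of at least 2-fold, each the count of 1 of the 10 splits, and the highest of the others gave 0 for both. Every other split holds both strains on each side, so the strain difference adds to the spread within its sides. Few calls could pass there, and the 0 does not measure chance. For gene lists the real split gave 11, and 2 of the 10 splits gave as many, with 11 in the highest of the others and 2 in the lowest. The number of lists called by camera at its preset correlation therefore does not set the real grouping apart from the others. The other splits hold unequal numbers of each strain on their sides, so part of the strain difference remains in them. They therefore cannot show how many lists would be called with no strain difference.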
